A study of Homo sapiens with 8 samples.

How the data were processed

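RNA-seq was analysed for 6 MCF-7 libraries, 3 labelled wild type (WT) and 3 labelled ZNF652 knockout. MCF-7 is an estrogen receptor positive human breast adenocarcinoma line, and the knockout was made with CRISPR-Cas9, per the labels. Total RNA was extracted with a column kit and made into Illumina libraries, per the labels' protocols; whether the libraries mark strand is not given in the sources used here. A ZNF652 chromatin immunoprecipitation library and its input are also among the samples and were not analysed here.

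The authors deposited estimated counts per transcript for each library, with TPM, transcript length and effective length beside them, per the file headers. The submitters' processing notes name kallisto 0.46, CASAVA and the genome build hg38; the transcript set is not given in the sources used here. kallisto assigns reads to transcripts by shared short sequence words and divides reads that fit several transcripts, so the values of near-identical copies and of isoforms of one gene are uncertain. The deposited TPM values, which are scaled to the same total in each library, were used here only for the transcripts of ZNF652 and CD274.

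The authors also deposited a table of whole-number values for 35587 gene symbols in the 6 libraries. These values equal the estimated counts summed per symbol, within 0.51 counts in all 6 libraries, for 98.51% of the 35264 genes that could be compared. They are therefore estimated counts rounded to whole numbers, and they were used as deposited. No row lacked a gene name. For transcripts, the deposited estimates were rounded to whole numbers here. Of 188753 transcripts, 89.93% matched GENCODE release 29 (GRCh38) by identifier, and the matched transcripts held at least 97.19% of the estimated reads in each library. Gene positions, identifiers and isoform types come from that annotation.

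Gene table totals ran from 17915503 to 45226490 counts per library. A floor of 3 counts corresponds to 0.0663 to 0.1675 CPM (counts scaled to a common library total), and floors and counting intervals cover counting error only. CPM were computed on library sizes scaled by TMM (trimmed mean of M values). Counts of libraries in the same group differed by far more than sampling noise in a chi-square comparison, with statistics of 41.9 to 233 per gene, so no library was treated as a repeat of another. Nothing in the labels says whether the 3 libraries of a group come from separate cultures or clones. The p-values then measure only the spread between these libraries, which may be technical.

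Genes were tested in R 4.3.3 with edgeR 4.0.16 (TMM, filterByExpr by group with its default minimum count of 10, robust dispersions, quasi-likelihood F-test, two-sided, group as the only term). The threshold was a Benjamini-Hochberg adjusted p under 0.05, and 15688 genes were tested. The CD274 gene lies below the count filter, and its values come from a fit in which it was added to the filtered genes. Transcripts were tested in the same way. Standard errors of log2 fold changes were taken from the fold change and its F statistic. Before the data were examined, 38 gene lists were fixed. They were tested with camera in limma 3.58.1 (preset correlation of 0.01, log2 CPM with a prior count of 2), two-sided and adjusted over the lists, with at least 5 tested members required. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera called no list in any comparison where it was run, so a call lost under it says little about a single list. Single values were compared with an exact two-sided permutation test over the 6 libraries, for which the smallest possible p is 0.1.

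Genes were named by a rule also fixed before the data were examined. It takes ZNF652, CD274 and the corepressor gene CBFA2T3 whatever their values. It also takes the 12 largest rises and 12 largest falls past the threshold among genes with a mean of at least 5 CPM and groups that do not overlap. From each list it takes up to 4 members with the smallest p, of which not all are printed. No gene met the second part in the planned fit. Genes named from DESeq2 1.42.0 or from fits added later were chosen after their values were seen, and are introduced with the fit they come from.

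The mean fragment length that kallisto used was recovered from the lengths and effective lengths of transcripts over 2000 nt. It parted the libraries into 4 with shorter fragments and 2 with longer fragments, with both groups present in each batch. After this was seen, 3 fits were added. The first has the fragment-length batch as a term. The second uses the 4 libraries with shorter fragments alone. The third has the batch term with a per-library trend of log2 CPM on gene length taken out. For the remaining pair of libraries, knockout replicate 1 and WT replicate 3, log2 differences are given without a test, and a list's median is placed among 10000 random lists of the same size matched on mean expression.

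The alternatives chosen in advance were other normalizations, no count filter or a filter at a mean of 5 CPM, DESeq2, limma-voom, a replicate block, each library left out in turn, gene sums made here from the transcript estimates, and a transcript length offset. The gene test was tested on simulated data with the means, library sizes and dispersions of the 15688 real genes, of which 200 were changed by known folds. For the comparison of 3 WT with 3 knockout libraries, it recovered 6% of the genes changed by 1 on the log2 scale, 34% at 1.5, 68% at 2 and 96% at 3. It also made 13 false calls. The simulated data for this comparison held no fragment-length batch, and each gene was drawn independently. With the batch term these shares were 62%, 94%, 98% and 98%, with 13 false calls. In the 4 libraries they were 72%, 92%, 100% and 100%, with 35 false calls.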

Results

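The transcriptome of MCF-7 breast cancer cells was measured by RNA-seq in 3 WT libraries and 3 libraries from cells in which ZNF652, a zinc finger gene encoding a DNA-binding repressor, had been targeted with CRISPR-Cas9. The stated purpose was to find the genes that depend on ZNF652, and the title of the series ties its loss to PD-L1, the immune checkpoint ligand encoded by CD274. Depth was 37252256, 35602814 and 17915503 counts in WT replicates 1 to 3, and 21744666, 36125469 and 45226490 in knockout replicates 1 to 3. The libraries also differed in mean fragment length. It was 260.14 nt in WT replicate 3 and 280.73 nt in knockout replicate 1, and 188.65 to 208.59 nt in the other 4. These 2 libraries of longer fragments, 1 from each group, were also the shallowest and lay apart from the rest along the first principal component, which held 60.5% of the variance. Differences between the groups are therefore given over all 6 libraries, and within each of these 2 batches where it matters.

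**Figure D1:**
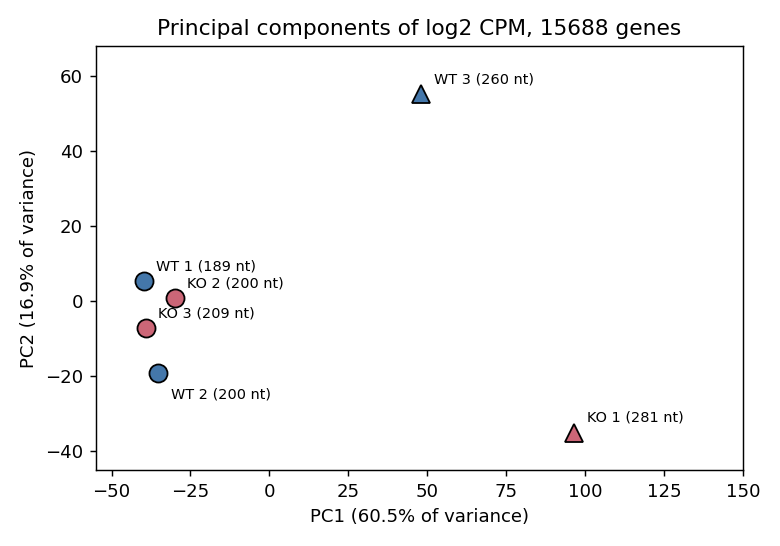
First and second principal components of log2 CPM over 15688 genes, 1 point per library, with WT in blue, ZNF652 knockout in red, circles for shorter and triangles for longer fragments. WT replicate 3 and knockout replicate 1 lie apart from the other 4 libraries on the first axis, which holds 60.5% of the variance.

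The targeted gene itself was still transcribed in the knockout libraries. ZNF652 (ENSG00000198740.8, chromosome 17, positions 49289206 to 49362473 on the minus strand, hg38) was at 51.0 ± 16.2 CPM (SD, n = 3) in WT and 33.3 ± 6.62 CPM (SD, n = 3) in knockout cells. The 3 WT libraries held 47.5, 36.9 and 68.7 CPM and the 3 knockout libraries 35.7, 38.5 and 25.9 CPM, so the groups overlapped. The log2 fold change was -0.61 with an SE of 0.28, and did not pass the edgeR test (adjusted p = 1; exact permutation p = 0.2). It was -0.38 within the 4 libraries of shorter fragments and -0.94 between the pair of longer fragments. Both annotated coding transcripts were present in every knockout library. That of 5988 nt had 286.2, 518 and 354.7 estimated counts there, and that of 4701 nt had 140.1, 146 and 183.2. The transcript annotated for nonsense-mediated decay averaged 7.56 ± 1.99 TPM in WT and 5.01 ± 1.26 TPM in knockout cells. An edit that shifts the reading frame can leave a transcript in place, so these levels neither bear out nor contradict the knockout labels.

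CD274 (ENSG00000120217.13, chromosome 9, positions 5450503 to 5470566 on the plus strand) was close to the limit of detection in every library. The WT libraries held 3, 6 and 0 counts and the knockout libraries 4, 16 and 20. This corresponds to 0.086 ± 0.088 CPM (SD, n = 3) in WT and 0.353 ± 0.151 CPM (SD, n = 3) in knockout cells, where 3 counts are worth 0.0663 to 0.1675 CPM. All 3 knockout libraries lay above all 3 WT libraries, although knockout replicate 1 (0.178 CPM) exceeded WT replicate 2 (0.177 CPM) by a margin far inside counting error. Summed per group, 40 counts in knockout against 9 in WT give a CPM ratio of 3.79, with an exact 95% counting interval of 1.81 to 8.88 that leaves out the spread between libraries. The fitted log2 fold change was 1.87 with an SE of 0.80 and did not pass the edgeR test (adjusted p = 1; exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). It was 1.77 within the 4 libraries of shorter fragments (edgeR adjusted p = 0.424). These values sum all transcripts of the gene. The coding transcript of 3634 nt held 0, 5.4 and 0 estimated counts in WT and 0, 0 and 8.5 in knockout libraries. That of 3343 nt held 2, 0 and 0 in WT and 2.1, 8.5 and 0 in knockout, so on each the groups overlapped. CD274-203, a processed transcript not annotated as coding, held 1, 0 and 0 in WT and 1.9, 3.3 and 6 in knockout. CD274-205 and CD274-204, also processed transcripts, held 0, 0.2 and 0 and 0, 0.4 and 0 in WT. In knockout they held 0, 3.3 and 2.8 and 0, 1 and 2.7. A large part of the rise thus lay outside the coding transcripts, on an uncertain division of few reads.

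**Figure D2:**
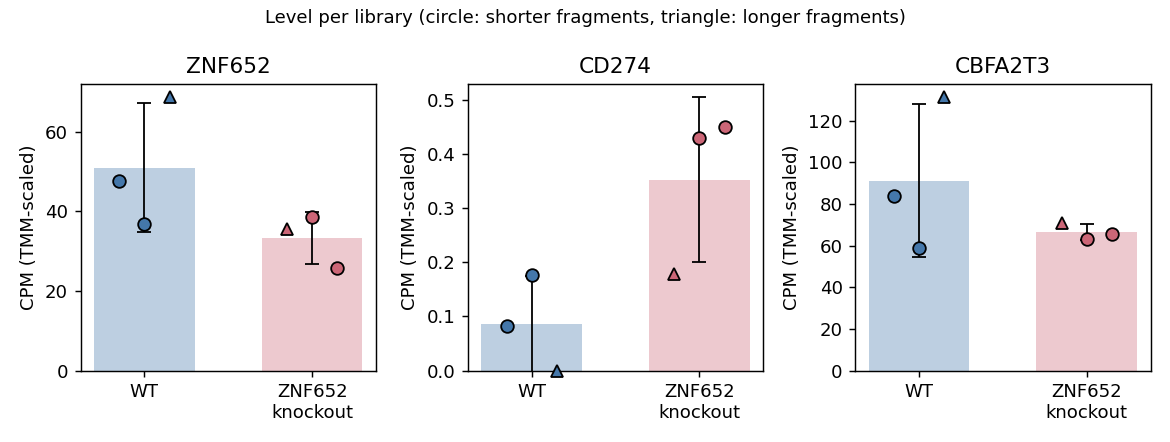
Level of ZNF652, CD274 and CBFA2T3 in CPM in each library, with bars for the group mean and error bars for the SD of 3 libraries, circles for shorter and triangles for longer fragments. ZNF652 overlaps between the groups, while CD274 lies at or below 0.45 CPM in every library and higher in the knockout libraries.

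Other immune checkpoint ligands showed no shared direction. Of 16 tested ligands, 8 were higher and 8 lower in knockout cells, with a median log2 difference of 0.03 (camera adjusted p = 0.958), and no member passed over all genes or adjusted over the list alone. NECTIN2, a ligand of TIGIT and PVRIG, was at 213 ± 19.7 CPM in WT and 174 ± 4.77 CPM in knockout cells, and ICOSLG, the ligand of the costimulatory receptor ICOS, at 9.47 ± 4.04 and 14.1 ± 2.12 CPM. Among 33 known regulators of PD-L1, 19 were higher and 14 lower (camera adjusted p = 0.297). The kinase subunit gene CSNK2A1 was at 118 ± 5.03 CPM in WT and 157 ± 7.16 CPM in knockout cells, and the interferon signal transducer STAT1 at 197 ± 53.9 and 256 ± 45.9 CPM, while AKT1 had a log2 fold change of -0.29. For STAT1 the log2 fold change was 0.37, but 0.05 within the 4 libraries of shorter fragments. All 3 genes missed the edgeR threshold (adjusted p = 1 for each). CBFA2T3, a corepressor of the ETO family known to partner ZNF652, was at 91.2 ± 36.8 CPM in WT and 66.6 ± 3.99 CPM in knockout cells (edgeR adjusted p = 1). WT replicate 3 held 131 CPM, and the log2 fold change went from -0.45 to -0.10 without that library and to -0.14 within the 4 libraries of shorter fragments. Its family and associated repressor complexes had 19 of 33 members higher (camera adjusted p = 0.569).

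No single gene passed the threshold of the edgeR quasi-likelihood test between knockout and WT. Of 15688 genes, 349 had an unadjusted p under 0.05, 169 of them higher and 180 lower in knockout cells. Chance alone gives a share of 0.05 in a well-calibrated test, and the share here was lower. With the fragment-length batch term the count was 1025, and among the 4 libraries of shorter fragments it was 1179. The planned fit thus looks conservative, and its 0 calls do not show that no gene differed. limma-voom also called 0 genes, and DESeq2 called 19. Groups that do not overlap were seen for 931 genes (5.93%). Chance gives 10% only if the 6 libraries are exchangeable. With a library of longer fragments in each group, overlap is likelier, so the share expected here is lower and was not estimated. Transcripts gave the same outcome in edgeR, with 0 of 68160 called and 664 at an unadjusted p under 0.05, again below the share that chance gives. The biological coefficient of variation common to all genes was 0.362, and in data simulated at that spread the test recovered 68% of genes changed by 2 on the log2 scale and 6% of those changed by 1.

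The genes that DESeq2 called were 8 higher and 11 lower. SPDEF (chromosome 6, positions 34537802 to 34556333), which encodes an ETS factor of luminal and secretory cells, was at 75.9 ± 22.9 CPM in WT and 11.6 ± 6.48 CPM in knockout cells (log2 fold change -2.70 in DESeq2, adjusted p = 9.24e-06). COL4A5, a basement membrane collagen gene, was at 13.4 ± 1.18 and 36.3 ± 6.54 CPM (DESeq2 adjusted p = 9.24e-06). IGF2, an insulin-like growth factor gene, was at 4.02 ± 0.685 and 20.7 ± 14.1 CPM. NES, which encodes the intermediate filament nestin, was at 7.58 ± 3.48 and 1.62 ± 0.80 CPM, and RIN1, PLS3 and UGT3A1 were also lower, with DESeq2 log2 fold changes of -2.58, -3.21 and -3.55. All of these missed the edgeR threshold over the same 6 libraries (adjusted p = 1), and 17 of the 19 passed it among the 4 libraries of shorter fragments.

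With the fragment-length batch as a term, a fit chosen after the batches were seen, 10 genes passed the edgeR threshold. The common coefficient of variation was then 0.218. ASCL1 (chromosome 12, positions 102957686 to 102960516), a proneural transcription factor gene, rose from 12.9 ± 4.58 to 45.1 ± 20.7 CPM (batch-term log2 fold change 1.77, SE 0.19, adjusted p = 0.0217). FOXI1 (chromosome 5, positions 170105897 to 170109725), a forkhead factor gene, rose from 0.656 ± 0.071 to 4.92 ± 2.06 CPM. WIPF1, an actin regulator gene, rose from 7.57 ± 2.28 to 24.9 ± 10.9 CPM, and COL4A5, UNC5C, CLEC3A and FAM84A were the others that rose. AGR2 (chromosome 7, positions 16791811 to 16833433), a protein disulfide isomerase gene of secretory epithelium, fell from 600 ± 199 to 226 ± 83.2 CPM (log2 fold change -1.45, SE 0.19, adjusted p = 0.0328). The prostate secretory gene MSMB and C9orf152 were the others that fell. The groups did not overlap for 6 of the 10 genes. Taking out a trend on gene length as well left ASCL1 alone past the threshold (adjusted p = 0.0413), although all 10 kept their direction and their adjusted p was at most 0.127. Their log2 fold changes hardly moved, as for AGR2 (-1.45, SE 0.19 before and -1.36, SE 0.19 after) and FOXI1 (2.88, SE 0.35 and 2.89, SE 0.34), and why the calls were lost was not tested.

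Among the 4 libraries of shorter fragments alone, 128 genes passed the edgeR threshold, 83 higher and 45 lower in knockout cells, a fit also chosen after the batches were seen and resting on 2 libraries per group. In simulated data of this size the same test made 35 false calls beside its true ones. The 10 genes called with the batch term were all among the 128. The naming rule was applied here with overlap judged in these 4 libraries only. Among the genes that met it, the rises included COL3A1 (log2 fold change 4.35, SE 0.23), the collagen chaperone gene FKBP10 (3.01, SE 0.26) and the lactate dehydrogenase gene LDHB (2.56, SE 0.24). Over all libraries the groups overlapped for these genes, and for BTG3 and AZGP1 named below. ARMCX2 (-3.74, SE 0.28), PABPC4L (-3.34, SE 0.29) and BTG3 (-2.84, SE 0.32) had the largest falls under that rule, which also named SPDEF (-2.12), TSPAN1 (-1.55), AZGP1 (-1.45) and AGR2 (-1.30). Between knockout replicate 1 and WT replicate 3, 74 of the 128 genes (57.81%, exact 95% interval 48.77% to 66.49%) went the same way. SPDEF, TSPAN1, AZGP1 and AGR2 did so, with log2 differences of -4.09, -3.94, -3.82 and -1.73. COL3A1, FKBP10, LDHB and BTG3 went the opposite way, at -2.81, -2.19, -0.61 and 1.34.

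**Figure D3:**
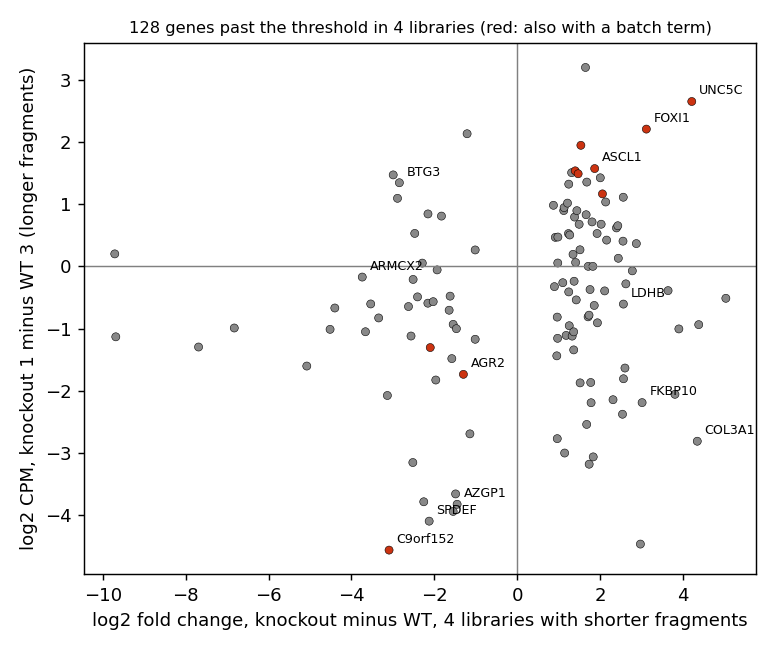
Log2 fold change between knockout and WT in the 4 libraries of shorter fragments (horizontal) against the log2 CPM difference between knockout replicate 1 and WT replicate 3 (vertical), 1 point for each of 128 genes past the threshold in the 4 libraries, red where the gene also passed with the batch term. 74 of the 128 lie on the same side of 0 on both axes, while COL3A1 is at 4.35 and -2.81. All 10 red genes are among the 74, but the fit that picked them used this pair, so that is no independent support.

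Interferon response genes stood higher in knockout cells as a group. Of 44 tested type I interferon response genes, 36 were higher, with a median log2 difference of 0.45, and camera placed the list above other genes (adjusted p = 1.82e-11 with its preset correlation). The call was lost with an estimated correlation (adjusted p = 0.654), and the preset correlation also called the list in 5 of the 9 other ways to split the 6 libraries into 3 and 3. In each of these 5 the list stood higher on the side with more knockout libraries, which a knockout difference would also give. OAS3, an antiviral oligoadenylate synthetase gene, was at 42.5 ± 6.42 CPM in WT and 82.5 ± 10.9 CPM in knockout cells. SAMD9 was at 3.77 ± 0.613 and 9.28 ± 3.12 CPM, PARP12 at 10.2 ± 1.19 and 21.5 ± 7.54 CPM, and the helicase gene DDX60 at 0.666 ± 0.112 and 2.78 ± 1.46 CPM. All 4 were higher in every knockout library than in any WT library, as were 12 of the 44 members in all, and none went the opposite way. Over all tested genes, the groups did not overlap for 5.93%, both directions together. No member passed the edgeR test over all genes or adjusted over the list alone in the planned fit. With the batch term, 9 passed adjusted over the list alone, and among the 4 libraries of shorter fragments 7 did. SAMD9 also passed there over all genes (edgeR adjusted p = 0.00836), and DESeq2 called OAS3 over the 6 libraries (adjusted p = 0.03385). The median difference was 0.26 within the 4 libraries of shorter fragments and 0.93 between the pair of longer fragments. With the preset correlation the call was kept without each library in turn.

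Of 25 interferon gamma response genes, 19 were higher (median log2 difference 0.27, camera adjusted p = 0.0268). The call was lost with an estimated correlation (adjusted p = 0.698). PIM1, a member, had a log2 fold change of -0.71. Of 14 tested MHC class I presentation genes, 10 were higher (camera adjusted p = 0.114), and 7 of 11 MHC class II genes (adjusted p = 0.209), so neither list passed in this fit. Between the pair of longer fragments their medians were 0.01 and -0.07, with 7 of 14 and 5 of 11 members higher. The peptide transporter genes TAP1 and TAP2 were at 5.50 ± 1.36 and 3.34 ± 0.656 CPM in WT and at 10.9 ± 1.67 and 7.27 ± 1.94 CPM in knockout cells, without overlap. CD74, the invariant chain gene, was at 0.371 ± 0.134 and 0.849 ± 0.347 CPM, while CALR and HLA-DRB1 both had log2 fold changes of -0.31. None of these genes passed the edgeR test (adjusted p = 1). The interferon gamma call was also lost without WT replicate 2 (adjusted p = 0.293), WT replicate 3 (0.244), knockout replicate 2 (0.215) or knockout replicate 3 (0.18).

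Targets of TNF and NF-kB were also higher as a list, with 21 of 28 members up and a median log2 difference of 0.22 (camera adjusted p = 0.0127). The call was lost with an estimated correlation (adjusted p = 0.698). BCL3 went against the list (log2 fold change -0.68), and the 3 members with a smaller p were cytokine genes of low level. LTB was at 0.093 ± 0.014 CPM in WT, about the level of 3 counts, and 0.435 ± 0.126 CPM in knockout cells. CSF1 was at 1.35 ± 0.885 and 4.25 ± 2.26 CPM, and CXCL8 averaged 0.597 ± 0.05 CPM in WT (log2 fold change 1.35, SE 0.62). CSF1 and CXCL8 passed the edgeR test among the 4 libraries of shorter fragments (adjusted p = 0.00228 and 0.0381), but their log2 differences between knockout replicate 1 and WT replicate 3 were -0.28 and -0.63. The list's median was 0.18 within the 4 libraries and 0.01 between the pair. Its call was also lost with a filter at 5 CPM (adjusted p = 0.339) and without WT replicate 2 (0.425), WT replicate 3 (0.115), knockout replicate 2 (0.117) or knockout replicate 3 (0.104).

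Mitotic genes were lower in knockout cells as a list. Of 53 G2/M genes, 49 were lower, with a median log2 difference of -0.26 (camera adjusted p = 0.00031). The call was lost with an estimated correlation (adjusted p = 0.698). BIRC5, which encodes survivin, was at 103 ± 25.3 CPM in WT and had a log2 fold change of -0.46 (SE 0.23), the kinase gene AURKB at 53.3 ± 6.19 CPM in WT and 41.3 ± 5.97 CPM in knockout cells, and UBE2C at 108 ± 11.4 and 84.9 ± 13.2 CPM. CCNB2 went the other way, at 43.9 ± 13.9 and 60.0 ± 5.86 CPM (log2 fold change 0.45). No member passed over all genes or adjusted over the list alone. The G1/S list had 41 of 50 members lower and missed the threshold (adjusted p = 0.0614). The G2/M median was -0.27 within the 4 libraries of shorter fragments and -0.10 between the pair, and the list was also lower in the 2 libraries of longer fragments than in the other 4 (median -0.35). Without WT replicate 2 its call was lost (adjusted p = 0.448).

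Hypoxia genes were lower as a list too, with 30 of 33 members down and a median log2 difference of -0.46 (camera adjusted p = 0.00138). An estimated correlation ended the call (adjusted p = 0.698). EGLN3, a HIF prolyl hydroxylase gene, was at 34.7 ± 11.2 CPM in WT and 13.4 ± 5.35 CPM in knockout cells, without overlap. GAPDH was at 7448 ± 3176 and 4685 ± 1164 CPM, and the glucose transporter gene SLC2A1 at 171 ± 28.9 and 116 ± 58.1 CPM. When each library was left out, the log2 fold change ran from -0.89 to -0.26 for GAPDH and from -0.92 to -0.20 for SLC2A1, whose knockout replicate 1 held 52.4 CPM. The median was -0.55 within the 4 libraries of shorter fragments and -0.02 between the pair. The list was also lower in the libraries of longer fragments than in the other 4 (camera adjusted p = 5.03e-06, and 0.824 with an estimated correlation). Without WT replicate 1 the list's direction turned (adjusted p = 0.802), and the call was lost without WT replicate 2 (0.0553) or knockout replicate 1 (0.347).

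Mitochondrially encoded genes were slightly lower, with 12 of 13 down and a median log2 difference of -0.21 (camera adjusted p = 0.0281). An estimated correlation ended this call too (adjusted p = 0.698). MT-ND4 and MT-ND4L, which encode subunits of respiratory complex I, were at 9535 ± 1416 and 1356 ± 220 CPM in WT and at 7500 ± 403 and 1054 ± 56.5 CPM in knockout cells. The median was -0.10 within the 4 libraries of shorter fragments, where 5 of 13 members were higher and the list missed the threshold (adjusted p = 0.341), and -0.54 between the pair. It was also lost without WT replicate 2 (0.321), WT replicate 3 (0.236), knockout replicate 1 (0.175) or knockout replicate 2. By fry, which asks whether a list moves on balance one way, 0 of the 38 lists passed (adjusted p = 0.838 for each of the 6 lists called by camera).

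**Figure D4:**
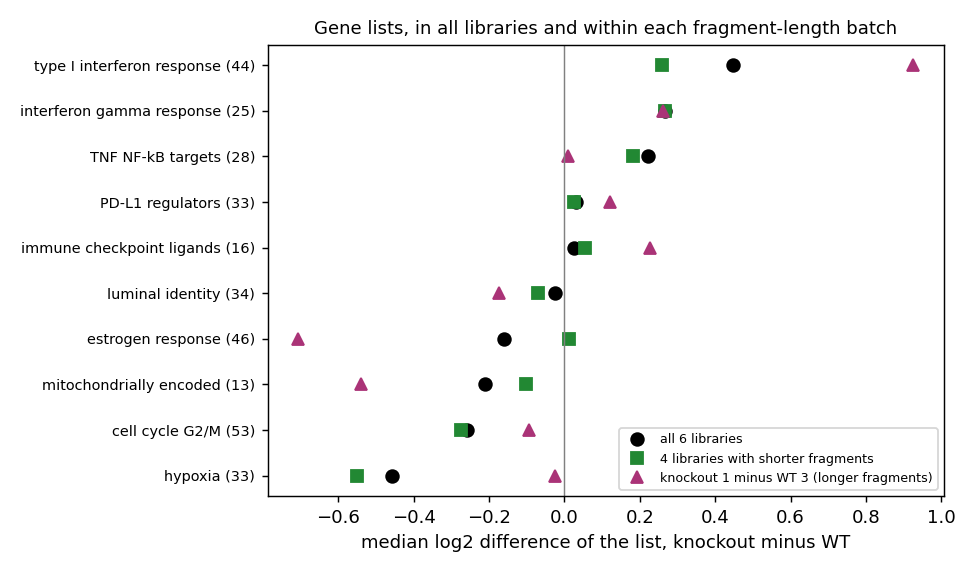
Median log2 difference between knockout and WT for the 6 gene lists called by camera and 4 others, with the number of tested genes in parentheses. Black circles show all 6 libraries, green squares the 4 libraries of shorter fragments and purple triangles the pair of longer fragments; the type I interferon list is above 0 in all 3, while hypoxia lies at -0.02 in the pair.

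Luminal identity genes went both ways. Of 34 tested, 16 were higher and 18 lower (camera adjusted p = 0.375), and 2 passed the edgeR test adjusted over the list alone, against 0 over all genes. These were SPDEF, given above, and EHF, an epithelial ETS factor gene, which was at 1.10 ± 0.192 CPM in WT and 3.26 ± 0.142 CPM in knockout cells. EHF was also called by DESeq2 (adjusted p = 0.0192) and among the 4 libraries of shorter fragments (edgeR adjusted p = 0.028). There, 3 luminal genes passed over all genes and 7 adjusted over the list alone, 2 of the 7 higher. AGR3 was at 66.7 ± 51.1 and 14.0 ± 9.32 CPM, without overlap. Estrogen response genes were lower for 31 of 46 members but missed the threshold (median log2 difference -0.16, camera adjusted p = 0.0867). Their median was 0.01 within the 4 libraries of shorter fragments and -0.71 between the pair. RAPGEFL1 was at 63.9 ± 8.40 CPM in WT and 31.8 ± 14.7 CPM in knockout cells, and the estrogen-induced gene TFF1 at 1804 ± 1203 and 770 ± 461 CPM, with a log2 fold change that ran from -1.54 to -0.54 when each library was left out. BCL2 went the other way, at 1.69 ± 1.41 and 6.60 ± 5.13 CPM (log2 fold change 1.95), and passed among the 4 libraries (edgeR adjusted p = 0.00594). Basal and myoepithelial genes were higher for 18 of 25 members (adjusted p = 0.112), among them TP63 at 0.898 ± 0.805 and 6.34 ± 7.76 CPM and KRT17 at 3.56 ± 1.51 and 7.53 ± 4.96 CPM. Most of the TP63 mean came from knockout replicate 1 (15.3 CPM, against 1.85 and 1.87 in the others), and its log2 fold change ran from 1.14 to 3.83 when each library was left out. The basal list passed among the 4 libraries (adjusted p = 0.0329), but not there with an estimated correlation (0.821).

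Lists of the mesenchymal program also missed the threshold. Epithelial-mesenchymal transition genes were higher for 20 of 32 members (camera adjusted p = 0.258), TGF-beta targets for 16 of 22 (0.258) and YAP targets for 13 of 16 (0.0548). YAP targets passed with the fragment-length batch term (adjusted p = 0.0167), but not with an estimated correlation as well (0.666). These 3 lists were also higher in the 2 libraries of longer fragments, with medians of 0.56, 0.65 and 1.04 against the other 4. CCN2 was at 0.444 ± 0.377 CPM in WT and 4.67 ± 7.47 CPM in knockout cells and F3, which encodes tissue factor, at 0.345 ± 0.107 and 1.41 ± 1.26 CPM, with 2.85 CPM in knockout replicate 1 and 0.752 and 0.608 in the others. The log2 fold change of F3 ran from 0.96 to 2.34 when each library was left out. TGFBI was at 41.6 ± 17.2 and 22.0 ± 3.12 CPM, lower in all knockout libraries, and COL1A1 had a log2 fold change of -0.60. COL3A1, a fibrillar collagen gene, was at 42.6 ± 26.0 and 377 ± 324 CPM, with a log2 fold change of 4.35 within the 4 libraries of shorter fragments (edgeR adjusted p = 1.89e-08) and -2.81 between the pair. Without knockout replicate 1 the fitted log2 difference of CCN2 was -0.21.

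Metabolic and growth factor lists missed the threshold. Cholesterol synthesis genes were higher for 13 of 25 members (adjusted p = 0.498), including CYP51A1 at 91.9 ± 12.9 CPM in WT and 125 ± 10.8 CPM in knockout cells and MSMO1 at 50.1 ± 8.84 and 66.7 ± 2.04 CPM, against TM7SF2 with a log2 fold change of -0.33. Fatty acid synthesis genes were higher for 7 of 15 (adjusted p = 0.759), with the lipid regulator gene SREBF1 at 171 ± 19.8 and 119 ± 13.1 CPM and FASN at 852 ± 306 and 557 ± 49.2 CPM, against FADS1 with a log2 fold change of 0.41. Among 31 receptor tyrosine kinases and ligands, 18 were higher (adjusted p = 0.536) and IGF2 alone passed adjusted over the list alone; ERBB3 was at 292 ± 20.6 and 233 ± 5.93 CPM. NES alone did so among 12 stem and progenitor genes, of which 8 were higher (adjusted p = 0.858). HEY2, a Notch target gene, was at 24.9 ± 1.73 and 12.8 ± 4.25 CPM in a list with 9 of 12 members lower (adjusted p = 0.0877), where JAG1 had a log2 fold change of 0.48.

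The remaining lists missed the camera threshold over the 6 libraries as well. p53 targets were higher for 25 of 38 members (adjusted p = 0.0877), cytokines and chemokines for 11 of 17 (0.209), MAPK feedback genes for 13 of 22 (0.536) and Wnt targets for 7 of 15 (0.58). Cytosolic ribosomal protein genes were lower for 36 of 42 members (0.0935), core histones for 13 of 19 (0.112), unfolded protein response genes for 24 of 34 (0.154), nuclear genes of oxidative phosphorylation for 33 of 42 (0.243), housekeeping genes for 12 of 17 (0.258) and genes neighbouring ZNF652 for 9 of 13 (0.482). Among the 4 libraries of shorter fragments, core histones (1 of 19 higher, adjusted p = 0.000223) and cytokines and chemokines (12 of 17 higher, 0.000415) passed, but not with an estimated correlation (0.821 for both), and between the pair their medians were 0.26 and -0.38, opposite in sign. Markers of cell types other than the cultured line missed it too. Immune cell markers were higher for 4 of 8 members (0.482), fibroblast markers for 7 of 9 (0.505), endothelial markers for 4 of 6 (0.356), neural markers for 4 of 5 (0.498), and hepatic and other epithelial markers for 2 of 5 (0.892). Fibroblast markers passed among the 4 libraries (0.03), but not there with an estimated correlation (0.821).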

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

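The fits with a fragment-length batch term, with the length trend taken out, and with the 4 libraries of shorter fragments were chosen after the data were seen. Over the 6 libraries, edgeR called 0 genes in the planned fit and under each other normalization, filter, gene sum and length offset, with 210 to 473 genes at an unadjusted p under 0.05 under the normalizations and filters, and limma-voom called 0. It also called 0 without each library in turn (range 0 to 0). DESeq2 called 19 (8 higher, 11 lower), the batch term gave 10 (7 higher, 3 lower), the batch term with the length trend taken out 1 (1 higher, 0 lower), and the 4 libraries 128 (83 higher, 45 lower). Genes past the threshold that met the naming rule numbered 0 in the planned fit, 9 with DESeq2, 4 with the batch term, 1 with the length trend taken out as well and 24 in the 4 libraries. For the 24, overlap was judged in those 4 libraries only. The cause of the difference between edgeR and DESeq2 was not tested. Transcripts gave 0 calls under each alternative run. Replicate numbers did not pair the samples: the correlations of their deviations from the group means were -0.505, 0.201 and -0.57 for replicates 1, 2 and 3, and not every library correlated best with its own number. The replicate block called 0 genes and 7 lists, with YAP targets (adjusted p = 0.0244) added to the 6. ZNF652 ranged from -0.80 to -0.34 on the log2 scale without each library, and from -0.65 to -0.38 under the other alternatives. CD274 ranged from 1.47 to 2.73 and from 1.77 to 3.12, and it has no value with a filter at 5 CPM or with the length trend taken out, since its counts are too low for those fits. Neither gene passed the adjusted threshold or turned. Of 75 genes checked, CCN2 alone turned. Its log2 fold change ran from -0.21 to 4.33 when each library was left out. In all, 34 of the 75 had a log2 fold change that grew or shrank by over 1.5 times on the log2 scale without some library. Beside ZNF652, CCN2 and the genes whose range is given above (GAPDH, SLC2A1, TFF1, F3 and TP63), these were STAT1 (0.19 to 0.58), ICOSLG (0.30 to 0.94), BIRC5 (-0.63 to -0.30), MT-ND4 (-0.44 to -0.22), MT-ND4L (-0.46 to -0.23), AGR3 (-2.72 to -1.45), RAPGEFL1 (-1.25 to -0.65), TGFBI (-1.15 to -0.54), FASN (-0.86 to -0.35). They also included UNC5C (1.56 to 5.70), CLEC3A (0.32 to 2.66), FAM84A (1.04 to 2.56), MSMB (-2.61 to -1.31), ARMCX2 (-3.49 to -1.61), BTG3 (-2.54 to -0.41), AZGP1 (-2.04 to -0.92), AKT1 (-0.37 to -0.15), CALR (-0.39 to -0.18). The others were HLA-DRB1 (-0.56 to -0.04), PIM1 (-0.99 to -0.28), BCL3 (-0.97 to -0.27), CCNB2 (0.29 to 0.74), COL1A1 (-0.93 to -0.43), TM7SF2 (-0.40 to -0.20), FADS1 (0.25 to 0.64), JAG1 (0.19 to 0.84) and CBFA2T3 (-0.69 to -0.10).

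Camera with its preset correlation called 6 of 38 lists, 0 with an estimated correlation and 0 by fry, where fry asks a different question, and 1 to 9 when each library was left out. A filter at 5 CPM gave 9, with TNF targets lost and MHC class I, G1/S and Notch targets (adjusted p = 0.0216 for each) and estrogen response (0.0285) gained, and an estimated correlation was not run with it. The batch term gave 7 and the 4 libraries 9. The 1 list called without WT replicate 2 was type I interferon response, and it is the only one of the 6 that was called without each library. Lists whose test turned direction missed the threshold in that setting. The adjusted p there was 0.974 by fry and 0.949 with the replicate block for checkpoint ligands, 0.723 for MAPK feedback, 0.943 for cytokines and 0.339 for stem genes with a filter at 5 CPM, and 0.818 for stem genes and 0.757 for hepatic markers with the batch term. In the 4 libraries it was 0.52 for estrogen response, 0.811 for TGF-beta targets, 0.846 for MAPK feedback, 0.127 for Wnt targets, 0.718 for stem genes and 0.494 for hepatic markers. The cause was not tested. Where leaving out 1 library turned a list, its adjusted p over the 6 such fits ran from 0.402 to 0.91 for checkpoint ligands, 0.0045 to 0.425 for estrogen response, 0.0424 to 0.91 for epithelial-mesenchymal transition, 0.0408 to 0.91 for TGF-beta targets, 7.36e-06 to 0.91 for G1/S, 1.62e-11 to 0.802 for hypoxia, 0.0656 to 0.949 for cholesterol synthesis, 0.357 to 0.938 for fatty acid synthesis, 0.00272 to 0.975 for oxidative phosphorylation, 0.112 to 0.802 for repressor complexes, 0.18 to 0.91 for receptor tyrosine kinases, 0.354 to 0.91 for MAPK feedback, 0.246 to 0.962 for Wnt targets, 0.000874 to 0.507 for YAP targets, 0.357 to 0.953 for stem genes, 0.246 to 0.91 for fibroblast markers, 0.229 to 0.842 for endothelial markers and 0.671 to 0.989 for hepatic markers. Depth limits CD274, LTB and other genes of a few counts, for which 3 counts are worth 0.0663 to 0.1675 CPM.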

Other observations

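The largest difference in these data lay between libraries within each group. Against the 4 libraries of shorter fragments, with group kept in the edgeR fit, WT replicate 3 and knockout replicate 1 differed in 3762 of 15688 genes, 1791 higher and 1971 lower. The genes named here were chosen after their values were seen. S100A7 averaged 0.05 CPM there and 26.6 ± 10.2 CPM (SD, n = 4) in the others, S100A8 averaged 2.47 and 61.5 ± 32.8 CPM, and the growth factor gene AREG, an estrogen target, 21.3 and 284 ± 35.5 CPM. TGFB2, which encodes a TGF-beta ligand, averaged 24.2 CPM in the 2 libraries and 0.34 ± 0.10 CPM in the others, the integrin gene ITGB6 averaged 37.7 and 3.30 ± 1.27 CPM, and the BMP target genes SMAD6 and ID1 52.6 and 125 CPM against 16.1 ± 0.72 and 39.8 ± 7.19 CPM. By camera with its preset correlation, hypoxia genes (2 of 33 higher), nuclear oxidative phosphorylation genes (9 of 42 higher, median -0.43), estrogen response genes (14 of 46 higher, median -0.72), G2/M genes and ribosomal protein genes were lower in the 2 libraries. Epithelial-mesenchymal transition genes (21 of 32 higher), TGF-beta targets (19 of 22), YAP targets (14 of 16) and repressor complex genes (25 of 33) were higher. None of these lists passed with an estimated correlation (adjusted p = 0.824 for each). EIF3CL, at 481.4 and 622.6 CPM in the 2 libraries and at most 7.3 CPM in the others, is a near-identical copy of EIF3C, so its value rests on how shared reads were divided. The sum of both copies was 1361.6 and 1582.9 CPM against 1041.7 to 1191.3 CPM.

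2 technical explanations were tested for these 2 libraries standing apart. Loss of short transcripts with longer fragments left a trace, since genes under 1000 nt had a median difference of -0.35 and genes over 3000 nt one of 0.22. Of 4531 genes over 3000 nt, 26.44% also differed (930 higher, 268 lower). CPM are relative, so a loss of short transcripts can raise longer ones, and these rises do not count against it. It does not account for the whole, because 268 of the longer genes were lower. Of the called genes under 1000 nt, 413 were lower but 89 higher. With the length trend taken out, 3207 genes were called, 2640 of them among the 3739 called before. Depth does not account for it either: with every library thinned to 17915503 counts, 94.68% of the genes were still called. A difference in culture, clone or library preparation stays open and was not tested, and the design names no biological group that divides the libraries in this way.

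The 128 genes called among the 4 libraries of shorter fragments were set against the remaining pair, with both tests chosen after the share was seen. Had the labels of WT replicate 3 and knockout replicate 1 been exchanged, at most 25% should go the same way in the pair. This holds only if the genes carry an effect shared by all knockout libraries. The share was 57.81%, where random genes of like expression gave a median of 49.22% (percentile 97.28 among 10000 draws). Genes without a shared effect would give a share near that median with or without an exchange. The share thus argues against an exchange only together with a shared effect, and an exchange by itself stays open. The same share (exact 95% interval 48.77% to 66.49%) argues against an effect on all of these genes shared by all 3 knockout libraries, for which at least 90% should go the same way, or 86.33% if the 35 false calls of the simulated data went either way, and 27 of the 54 genes that went the opposite way did so by over 1 on the log2 scale. The falls kept their direction more often (35 of 45) than the rises (39 of 83), a difference that was not tested. A knockout effect on part of the genes, such as the 10 called with the batch term, and differences between clones or cultures that the labels do not describe both stay open.

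Higher interferon genes in knockout cells may reflect the loss of ZNF652, a hypothesis found and examined on the same data, with the test of the batches chosen after its result was seen. The list passed camera without each of the 6 libraries in turn (6 of 6, medians from 0.30 to 0.58). It was also called in 5 of the 9 other splits of the libraries (adjusted p from 4.04e-06 to 0.0421). In each of these 5 it was higher on the side with more knockout libraries. A knockout difference would give such calls, as would spread between libraries, so they cannot tell these apart. The medians do not depend on that correlation and stayed above 0 without each library, so no 1 library supplied the whole difference. Whether what remains exceeds the spread between libraries stays open, since the calls without each library rest on the preset correlation. A batch difference shared by both groups could not carry it, since each group held 1 library of longer fragments. The median was above 0 within both batches, at 0.259 in the 4 libraries of shorter fragments and 0.925 in the pair. How much of the difference the pair supplies stays open, as it has 1 library per group. The real split gave a median of 0.446, the largest in size in 1 of 10 splits, with 0.4041 as the highest other, and 10 splits are too few for a share under 0.05. Coordinated spread between libraries stays open. With an estimated correlation, which allows for it, the call was lost (camera p = 0.0172 unadjusted and 0.654 adjusted over the lists). That setting called no list in any comparison where it was run, not even between the fragment-length batches, where 3762 genes differed. The lost call therefore does not show that such spread explains the list.

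For the counts of calls, 10 splits of the 6 libraries into 3 and 3 are likewise too few for a share under 0.05. The planned edgeR fit gave 0 genes in the real split and at most 1 in the others, so that 10 of 10 splits gave as many, and transcripts gave 0 in each of the 10. With the batch term the real split gave 10 genes and the highest other 1, so that 1 of the 10 gave as many. Camera with its preset correlation called 6 lists in the real split and up to 12 in the others, and 8 of the 10 splits gave as many. Other splits with both libraries of longer fragments on the same side gave 9, 8, 9 and 12 lists, and these partly compare the batches. Those with 1 on each side, like the real split, gave 6, 2, 5, 8 and 8. The highest other count of genes with the batch term also came from a split with 1 on each side. Calls of camera with its preset correlation are thus as many in most other splits as between knockout and WT.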
